A study of Mus musculus with 18 samples.

How the data were processed

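RNA-seq profiles of 18 mouse libraries in 9 groups of 2 were analysed, 8 from dermal papilla cells (DP) and 10 from hair follicle stem cells (HFSC), both purified by flow cytometry. Per the labels' protocols, cDNA was made with SMART-Seq v4 and libraries with Nextera XT, a chemistry that does not mark strand. For the DP libraries the authors deposited estimated counts per transcript, made with Salmon on mm10 per the submitters' processing notes. For the HFSC libraries the authors deposited whole-number read counts per gene, made per the file headers with featureCounts 1.6.1 over exons at a minimum mapping quality of 30 and without a strand setting. The submitters' processing notes name Trim Galore 0.4.1 and STAR 2.5.3 for these libraries and DESeq2 1.22.2 for both cell types. The 2 cell types were counted in different ways and were therefore never compared with each other.

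The 134967 DP transcripts were summed to genes through the GENCODE M21 annotation of GRCm38, the assembly that mm10 denotes, and the sums were rounded to whole numbers. A match failed for 150 transcripts, which held at most 0.0752% of the counts of a library, and 52958 gene symbols resulted. Of the 27933 HFSC gene symbols, 26711 were found in that annotation. Dates stood in place of 27 gene names in 2 of the HFSC files, and they were restored from the coordinates in the same line. Total counts were 6194415 to 13941628 per DP library and 14067139 to 33014976 per HFSC library. Reads without molecular identifiers are not independent molecules, so intervals and floors given for single genes cover counting error only. Reads of overlapping or antisense genes could not be told apart, and histone, keratin and ribosomal protein genes have near-identical copies whose counts are uncertain.

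Each cell type was fitted in 1 model with a mean per group in edgeR 4.0.16 under R 4.3.3, with TMM scaling, the default filter on low counts and the quasi-likelihood test, and p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The filter kept 23463 DP and 15231 HFSC genes. The biological coefficient of variation was 54% in DP and 38.7% in HFSC, on 4 and 5 residual degrees of freedom. Standard errors of log2 fold changes were derived from the F statistic, and CPM values are counts relative to the scaled library sizes, as edgeR gives them. Gene lists, 33 in number with 594 distinct genes, were written before the data were examined, as were the groups, the tests and the rule for naming genes. They were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation. No list passed in any of the 6 comparisons with an estimated correlation.

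Genes were named by a fixed rule. In each comparison it took up to 10 genes per direction with the largest log2 fold change among those past the threshold, with a mean of at least 5 CPM in the higher group and no overlap between the libraries of both groups, leaving out predicted or clone-named genes, pseudogenes and genes without a symbol. It added Nr3c1, Gas6, Axl, Fkbp5, Tsc22d3, Zbtb16 and Per1, up to 4 members of each list with the smallest p-values, and the 5 genes with the smallest p-values under the same filters on expression and name where fewer than 10 passed. Shared or reversed calls were ranked by the smaller of both changes, and for differences between effects up to 5 genes per sign were taken without the condition on overlap.

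Alternatives listed at the same time were DESeq2 1.42.0, median-of-ratios scaling, no filter on low counts, a fit of only the groups compared, the replicate number as a block, and leaving out each library in turn. An arm left with a single library was assumed to vary like the other groups. Alternatives chosen after the data were seen were an offset for GC content and transcript length (a spline with 4 degrees of freedom per library and property), protein-coding genes only in DP, libraries of the same experiment only in HFSC, and crossed replicate numbers. A GC value was found for 100% of the DP and 97% of the HFSC genes tested.

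The steps were tested on simulated counts with the means, library sizes and dispersions of the real genes, in which 200 genes above 5 CPM were changed by 2-fold, 4-fold or 8-fold. Each gene was drawn independently, so the simulations hold no deviations that many genes of a library share. Their shares of false calls may therefore be too low for real libraries. For adrenalectomy in DP, 3%, 37.3% and 71.2% of genes of these sizes were called. For GR deletion in DP the shares were 3%, 34.3% and 84.8%, and for the difference between both effects 0%, 6% and 51.5%. In HFSC they were 25.4%, 79.1% and 100% for adrenalectomy, 26.9%, 88.1% and 97% for corticosterone against adrenalectomy, 14.9%, 85.1% and 97% for corticosterone against sham, 25.4%, 88.1% and 93.9% for GR deletion, and 9%, 62.7% and 84.8% for the difference. Among the simulated calls of a comparison, 2.65% to 21.6% were of genes that had not been changed, above 5% in 7 of the 8 comparisons. A list of 34 genes raised 2-fold passed camera at the preset correlation in each of these simulations. With an estimated correlation it was missed for adrenalectomy in DP (adjusted p = 0.733), for GR deletion in DP (adjusted p = 0.0752) and for the difference in DP (adjusted p = 0.433), while in the 5 HFSC comparisons it passed (adjusted p = 0.00219 to 0.015). At the preset correlation 1 other list was called in 3 of the 8 simulations, those of GR deletion in DP, the difference in DP and adrenalectomy in HFSC. The labels do not say that replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical. Replicates differed by more than sampling noise in each group, with a chi-square per degree of freedom of 23.5 to 95.3.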

Results

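The series measured gene expression in 2 cell populations of mouse skin. Dermal papilla cells (DP) form the signalling centre at the base of the hair follicle, and hair follicle stem cells (HFSC) are the epithelial cells that regrow the follicle. Mice were sham-operated or adrenalectomised (ADX), which removes the main source of corticosterone, and in HFSC a further group was adrenalectomised and given corticosterone (ADX+CORT). In a separate pair of groups the glucocorticoid receptor (GR, encoded by Nr3c1) was deleted in Pdgfra-expressing dermal cells by tamoxifen over 6 days (GR KO), next to controls. Those controls received tamoxifen as well, and the surgery and deletion experiments also differed in mouse strain. Each of the 9 groups had 2 libraries, with 6194415 to 13941628 counts per library in DP and 14067139 to 33014976 in HFSC. The title of the series names the question, which is whether corticosterone restrains Gas6, a secreted ligand of the TAM receptor kinases, and through it the activity of HFSC.

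The deleted gene was examined first. Nr3c1 (chromosome 18 of GRCm38) fell in GR KO DP by 2.73 on the log2 scale (SE 0.38), from 825 ± 217 CPM in Control (SD, n = 2) to 124 ± 17.9 CPM (SD, n = 2), with an edgeR adjusted p = 0.0212. By library it stood at 671 and 978 CPM in Control DP, 137 and 111 CPM in GR KO DP, 671 and 365 CPM in Sham DP, and 367 and 537 CPM in ADX DP. Without Control DP replicate 2 the log2 fold change was −2.62 with an edgeR adjusted p = 0.0589, and over the alternatives that p was 1.28e-16 to 0.0589. After adrenalectomy the DP value was −0.20 (SE 0.36, edgeR adjusted p = 0.863), and it was 0.27 without Sham DP replicate 1. In HFSC the libraries held 257 and 338 CPM in Control, 243 and 170 in GR KO, 421 and 399.8 in Sham, 267 and 266 in ADX, and 388 and 319 in ADX+CORT. The change after GR deletion there was −0.53 (SE 0.24, edgeR adjusted p = 0.367).

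Gas6 (chromosome 8, 13465374 to 13494490 on GRCm38) stood at 543 ± 127 CPM in ADX DP and 149 ± 13.6 CPM in Sham DP (SD, n = 2 each). The log2 fold change was 1.87 (SE 0.38) and did not pass the threshold in edgeR (adjusted p = 0.183). In GR KO DP it stood at 970 ± 514 CPM against 328 ± 40.4 CPM in Control, a log2 fold change of 1.57 (SE 0.38, edgeR adjusted p = 0.0734). In both comparisons each library of the altered group lay above both of its controls. Among the 8 TAM receptors and ligands fixed beforehand, Gas6 rose in both comparisons when adjusted over the list alone (edgeR adjusted p = 0.00489 and 0.00783). The series title names Gas6, so the list was not chosen blind to it and these values are no independent support. The related ligand Pros1 rose in GR KO DP over all genes tested (1.39, SE 0.28, edgeR adjusted p = 0.0463), a call lost without each of the 4 libraries (0.176 and 0.538 without Control replicates 1 and 2, 0.0787 and 0.147 without GR KO replicates 1 and 2). In ADX DP, Pros1 and the receptor Axl fell when adjusted over the list alone, by 1.08 and 0.99. In GR KO DP, 1 gene of the list fell when adjusted over the list alone. The list did not pass in camera in either comparison (medians −0.37 and 1.36, adjusted p = 0.318 and 0.13). DESeq2 called both changes of Gas6, with an adjusted p = 0.000308 after adrenalectomy (range over the alternatives 5.91e-07 to 0.304) and 0.00467 after GR deletion (range 0.000233 to 0.473). Without GR KO DP replicate 1 the value after GR deletion was 0.90, and without GR KO DP replicate 2 it was 2.04 with an edgeR adjusted p = 0.0304. The difference between both effects was 0.30 (SE 0.52, edgeR adjusted p = 0.864). In HFSC, Gas6 had log2 fold changes of −0.35 after adrenalectomy (SE 0.24, edgeR adjusted p = 0.515), 0.59 in ADX+CORT against ADX (SE 0.24, edgeR adjusted p = 0.206) and −0.01 after GR deletion (SE 0.24, edgeR adjusted p = 0.996). The TAM list fell in camera in GR KO HFSC (7 of 8 lower, 1 fallen when adjusted over the list alone, median −0.24, adjusted p = 0.0497, and adjusted p = 0.336 with an estimated correlation), but not without Control replicate 1 or 2 or GR KO replicate 2 (adjusted p up to 0.44).

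**Figure D1:**
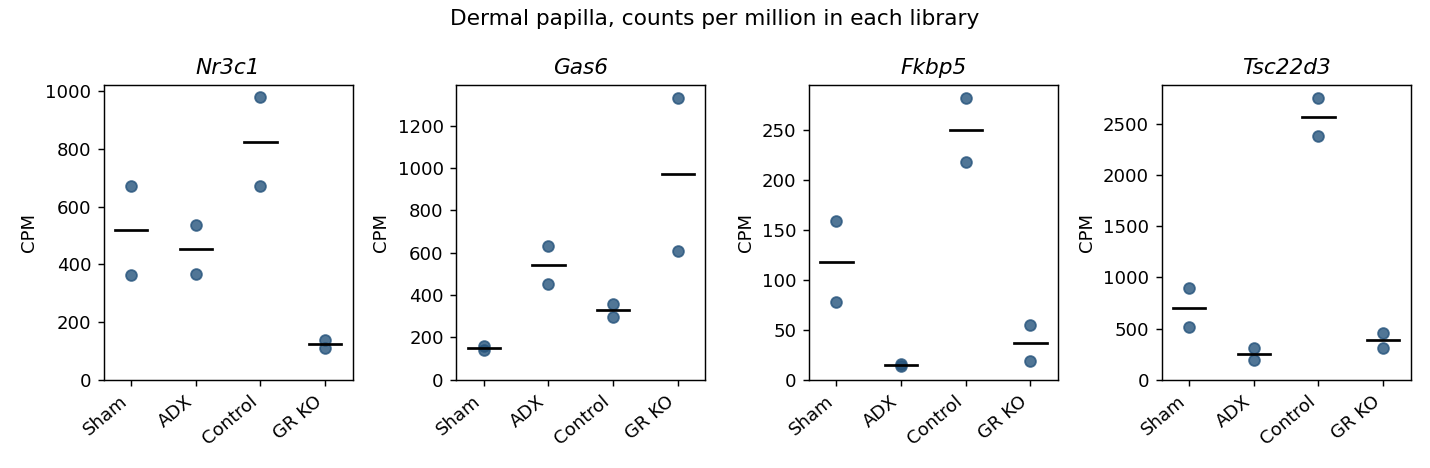
Levels in CPM of Nr3c1, Gas6, Fkbp5 and Tsc22d3 (vertical axes, linear from 0) in each of the 8 DP libraries, by group; points are libraries and bars are means of 2. Gas6 had means of 149 CPM in Sham, 543 in ADX, 328 in Control and 970 in GR KO, and Nr3c1 had means of 825 CPM in Control and 124 in GR KO.

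In DP after adrenalectomy, Sox18, a transcription factor of endothelium and dermal papilla, rose from 18.1 ± 3.25 to 187 ± 2.59 CPM (SD, n = 2 each), a log2 fold change of 3.37 (SE 0.29, edgeR adjusted p = 0.00923). Ramp3, a partner of the calcitonin-like receptor, rose by 3.92 (SE 0.38, adjusted p = 0.0145). Scnn1g, a subunit of the epithelial sodium channel, rose as well, from 1 read in both Sham libraries to 290 in both ADX libraries. That is a ratio of 472, with an exact 95% counting interval of 84.1 to 18700. Aldh1a1, a retinaldehyde dehydrogenase, fell by 3.40 (SE 0.36, adjusted p = 0.0184). These were the 4 genes that passed in edgeR, against 467 in DESeq2 (197 rose and 270 fell) and 2737 at an unadjusted p under 0.05. The call was lost for Sox18 without Sham replicate 2 (edgeR adjusted p = 0.0593), for Ramp3 without Sham replicate 1 or 2 (0.0834 and 0.076), for Scnn1g without Sham replicate 1 or 2 (0.0645 and 0.0593), and for Aldh1a1 without Sham replicate 2 or ADX replicate 1 (0.0593 and 0.0662). The count was 5, 1, 4 and 12 without Sham replicate 1, Sham replicate 2, ADX replicate 1 and ADX replicate 2, 7 with the replicate number as a block, and 0 in a fit of only these 2 groups.

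Targets of glucocorticoids were lower as a group in ADX DP. Of 31 glucocorticoid-induced genes none passed over all genes tested, 13 fell when adjusted over the list alone, and 26 had lower values. The list fell in camera with a median log2 fold change of −0.83 (adjusted p = 5.28e-11), and adjusted p = 0.414 with an estimated correlation. Fkbp5, a chaperone that limits GR signalling, stood at 14.7 ± 1.56 CPM in ADX and 118 ± 57.5 CPM in Sham (SD, n = 2 each, edgeR adjusted p = 0.139). Tsc22d3 had a value of −1.51 (SE 0.37) and Klf9 one of −1.72 (SE 0.33). In camera the 21 immediate early and heat shock genes (median −0.73, adjusted p = 5.85e-09), the 32 matrix genes (median −0.47, adjusted p = 1.99e-06) and the 18 cholesterol synthesis genes (median −0.71, adjusted p = 1.99e-06) also fell, each with adjusted p = 0.414 with an estimated correlation. Adjusted over the list alone, 7, 3 and 4 of their members fell. They included the immediate early genes Nr4a1 and Egr1 (−1.21 and −1.12), the collagenase-related Mmp3 (−4.25) and Fdps of the mevalonate pathway (−1.70).

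Markers of other cells moved with the same comparison. The 18 genes of the differentiated epidermis and upper follicle were all lower in ADX DP (median −2.66, camera adjusted p = 1.12e-09, adjusted p = 0.414 with an estimated correlation), and 10 fell when adjusted over the list alone. Krt10 had a value of −2.90 and Ivl one of −3.66. The 20 dermal fibroblast genes fell in camera (median −0.55, adjusted p = 4.49e-06, and adjusted p = 0.414 with an estimated correlation). The 13 pericyte and smooth muscle genes rose in camera (median 2.44, adjusted p = 1.88e-06, and adjusted p = 0.414 with an estimated correlation), 9 of them when adjusted over the list alone, with Acta2 at 1991 ± 2029 CPM in ADX and 118 ± 21.3 CPM in Sham. G2 and M phase genes rose in camera (median 1.58, adjusted p = 1.58e-06, and adjusted p = 0.497 with an estimated correlation), but not without ADX DP replicate 1 (adjusted p = 0.131).

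In DP, edgeR called 361 genes after GR deletion and 4 after adrenalectomy. At an unadjusted p under 0.05 it had 3574 and 2737. Replicates correlated less in Sham and ADX (Pearson 0.881 and 0.882 of log2 CPM) than in Control and GR KO (0.962 and 0.947). Chi-square per degree of freedom did not follow this order (56.1, 34.3, 49.9 and 73.9). ADX libraries held 6194415 and 7784321 counts, other DP libraries 11329227 to 13941628. Genes detected were 33638 and 32048 in ADX, 27093 and 32511 in Sham, and 24517 to 26506 in Control and GR KO. Reads of chromosome Y stood at 603 and 750 CPM in ADX, 367 and 394 in Sham, and 67.3 to 111 in Control and GR KO. The cause of these differences was not tested. The gap in calls alone therefore does not show a larger effect. As lists, matrix genes rose and glucocorticoid targets fell after GR deletion. In edgeR 180 genes rose and 181 fell, against 719 and 654 in DESeq2. With median-of-ratios scaling the split was 134 and 247, and the median of all genes moved from 0.17 to 0.07. Ribosomal protein genes made up 43 of the 181 that fell in edgeR, with 103 of 112 lower. Their median was −1.52, or −1.03 with an offset for GC content and transcript length. Of the 31 glucocorticoid-induced genes, 10 fell, 21 did not pass, and 19 fell when adjusted over the list alone (median −1.41, camera adjusted p = 6.44e-20, and adjusted p = 0.198 with an estimated correlation). Tsc22d3, which encodes the anti-inflammatory protein GILZ, fell by 2.74 (SE 0.39, edgeR adjusted p = 0.0212), Fkbp5 by 2.77 (SE 0.51, adjusted p = 0.0373), Angptl4 by 2.70 (SE 0.30, adjusted p = 0.0165), Cebpd by 2.13 (SE 0.36) and the clock gene Per1 by 1.75 (SE 0.29, adjusted p = 0.0312). Per2, which belongs to the clock list, rose by 2.46 (SE 0.51, adjusted p = 0.0481). Without Control replicate 2 the calls of these genes were lost except that of Angptl4, with edgeR adjusted p-values from 0.0502 for Tsc22d3 to 0.481 for Per2. Per1 was lost without each of the other 3 libraries (0.0759 to 0.124), Cebpd without either GR KO replicate (0.0922 and 0.0759), Fkbp5 without GR KO replicate 2 (0.074), and Per2 without Control replicate 1 or GR KO replicate 1 (0.232 and 0.348).

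Of 32 matrix and matrix remodelling genes, 12 rose, 20 did not pass, and 25 rose when adjusted over the list alone. Their median was 1.72 (camera adjusted p = 3.2e-25, and adjusted p = 0.0852 with an estimated correlation). Postn, a matricellular protein, rose from 339 ± 102 to 2501 ± 852 CPM (SD, n = 2 each), a log2 fold change of 2.88 (SE 0.42, edgeR adjusted p = 0.0212). Timp1 rose by 2.89 (SE 0.49), Col5a2 by 1.88 (SE 0.28) and Col1a2 by 2.18 (SE 0.44), each past the threshold in edgeR. The dermal fibroblast list moved with them, with 4 of 20 genes risen, 10 risen when adjusted over the list alone and a median of 1.28 (camera adjusted p = 2.98e-08, and adjusted p = 0.291 with an estimated correlation). Sparc, which is on both lists, rose by 1.92, and Cd34, which is on the fibroblast and stem cell lists, by 2.14. Among 18 cholesterol synthesis genes 4 rose, 7 when adjusted over the list alone (median 0.81, camera adjusted p = 7.38e-07, and adjusted p = 0.407 with an estimated correlation). They included Hmgcs1 (2.30, SE 0.27, edgeR adjusted p = 0.0192) and Cyp51 (1.91, SE 0.31). Without Control replicate 2 none of the genes named here passed, with edgeR adjusted p-values from 0.0843 for Postn to 0.458 for Sparc. Calls were also lost without Control replicate 1 for Postn, Col5a2, Sparc and Cyp51 (0.0556 to 0.199), without GR KO replicate 1 for Timp1, Col1a2, Sparc and Cyp51 (0.0558 to 0.0859), and without GR KO replicate 2 for Col1a2 and Sparc (0.0846 and 0.117).

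Some genes of the differentiated epidermis list fell in GR KO DP. Lor, the main protein of the cornified envelope, fell by 5.95 (SE 0.68, edgeR adjusted p = 0.0165) and Cst6 by 6.16 (SE 1.07, adjusted p = 0.0344). The list held 2 genes that fell, 16 that did not pass, 13 of 18 that were lower and 6 that fell when adjusted over the list alone (median −1.72, camera adjusted p = 6.18e-10, and adjusted p = 0.407 with an estimated correlation). Wfdc21 had no read in GR KO, at least 66.6-fold lower than Control against a floor of 3 reads over the group, and Fam151a had none in Control and was at least 246-fold higher in GR KO. Sprr4 had 3 reads in GR KO and 540 in Control, a ratio of 198 with a 95% counting interval of 67.3 to 962. Genes that rose included Bhmt (7.14, SE 1.18), Ptgs2, which encodes cyclooxygenase 2 (5.41, SE 1.10), Smoc1 (4.36, SE 0.88) and the chemokine Ccl2 (3.16, SE 0.58). Agtr2 fell by 4.53 (SE 0.62), Galnt15 by 4.98 (SE 0.75) and the beta-adrenergic receptor Adrb3 by 4.02 (SE 0.52). All 7 passed in edgeR, with adjusted p-values of 0.0212 to 0.0475. Interferon response genes rose in camera (20 of 22 higher, 8 risen when adjusted over the list alone, median 0.90, adjusted p = 1.5e-05, and adjusted p = 0.291 with an estimated correlation). Immune cell genes were higher in the same comparison (18 of 18, none called, median 2.13) without passing in camera (adjusted p = 0.149, and adjusted p = 0.832 with an estimated correlation). They passed upward without Control replicate 1 or GR KO replicate 2 (adjusted p = 0.0237 and 4.81e-30) and downward without GR KO replicate 1 (median −2.84, adjusted p = 5.91e-15). Mitochondrial respiratory chain genes fell (20 of 24 lower, median −0.45, adjusted p = 0.0002, and adjusted p = 0.407 with an estimated correlation), with Cox4i1 at −1.66 (SE 0.32, edgeR adjusted p = 0.0423). G2 and M phase genes rose in camera (33 of 34 higher, median 2.42, adjusted p = 3.64e-11, and adjusted p = 0.407 with an estimated correlation). Skeletal muscle genes rose in camera (13 of 14 higher, 7 risen when adjusted over the list alone, median 3.38, adjusted p = 0.0111, and adjusted p = 0.645 with an estimated correlation), with Atp2a1, the calcium pump of fast muscle, at 24.4 ± 32.1 CPM in GR KO and 0.69 ± 0.08 CPM in Control. Without GR KO replicate 1 that list had an adjusted p = 0.346 and the opposite direction. Without Control replicate 2 only Lor, Cst6 and Adrb3 among the called genes named here passed, the others having edgeR adjusted p-values from 0.0524 for Galnt15 to 0.419 for Ptgs2. Ptgs2, Smoc1, Ccl2, Fam151a and Sprr4 were also lost without Control replicate 1 (0.0744 to 0.214), the same 5 with Cox4i1 and Wfdc21 without GR KO replicate 1 (0.0516 to 0.258), and Smoc1, Cox4i1, Wfdc21 and Sprr4 without GR KO replicate 2 (0.0627 to 0.109). The count of 361 genes was 142 in a fit of only these 2 groups, 226 without Control DP replicate 1, 19 without Control DP replicate 2, 192 without GR KO DP replicate 1 and 213 without GR KO DP replicate 2.

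Sox18 was called in the same direction in both DP comparisons, with a log2 fold change of 2.42 (SE 0.28, edgeR adjusted p = 0.0165) after GR deletion, or 0.0862 without Control replicate 2. Scnn1g was called in opposite directions, since it fell from 22.2 to 2.76 CPM after GR deletion (edgeR adjusted p = 0.048), a call lost without each of these 4 libraries (0.0833 and 0.348 without Control replicates 1 and 2, 0.205 and 0.129 without GR KO replicates 1 and 2). No other gene was called in both, and DESeq2 gave 61 calls shared in direction. Independent lists of these sizes would share 0.02 risen genes (Fisher's exact test, p = 0.0228). That p-value treats genes as independent. Over all genes tested, the log2 fold changes of both comparisons had a Pearson correlation of 0.068. At an unadjusted p under 0.05, 142 genes were higher in both comparisons and 134 lower in both, while 362 were lower after adrenalectomy and higher after GR deletion and 56 the other way. The effects differed for 112 genes in edgeR, with 30 more positive after adrenalectomy and 82 more positive after GR deletion, and 45 and 46 with median-of-ratios scaling. A dependence on strain or tamoxifen cannot be told apart from these differences, because both differ between the experiments. Postn had a difference of −4.53 (SE 0.58, edgeR adjusted p = 0.0245) and Ramp3 one of 5.19 (SE 0.51, adjusted p = 0.0156). Both calls were lost without Sham replicate 2 (0.0822 and 0.0796), and that of Postn also without ADX replicate 2 or Control replicate 2 (0.0629 and 0.0592). Of 32 matrix genes each had a negative difference, and 4 passed (median −2.38, camera adjusted p = 1.33e-27, and adjusted p = 0.0778 with an estimated correlation). The count of 112 was 3 without Sham replicate 2, 19 without ADX replicate 2, 26 without Control replicate 1, 3 without Control replicate 2 and 221 without GR KO replicate 2. The shared count was 0 without Sham replicate 2 and 5 without Control replicate 2 or GR KO replicate 1. It was 2 without Sham replicate 1 or Control replicate 1, and 3 without ADX replicate 2.

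In HFSC, adrenalectomy was followed by higher expression of cell division genes. The cyclin Ccnb2 rose from 6.74 ± 0.56 to 60.7 ± 32.0 CPM (SD, n = 2 each), a log2 fold change of 3.17 (SE 0.55, edgeR adjusted p = 0.0393). Birc5, which encodes the mitotic protein survivin, rose by 2.97 (SE 0.51, adjusted p = 0.0393). Of 34 G2 and M phase genes 2 rose and 32 did not pass, 31 rose when adjusted over the list alone, and 34 of 34 were higher (median 2.19, camera adjusted p = 3.08e-26, and adjusted p = 0.593 with an estimated correlation). S phase genes rose in camera too, with 31 of 33 higher and 11 risen when adjusted over the list alone (median 0.93, adjusted p = 5.75e-09, and adjusted p = 0.614 with an estimated correlation). Hair follicle stem cell genes fell as a list, with 20 of 27 lower and 5 fallen when adjusted over the list alone (median −0.40, camera adjusted p = 0.00133, and adjusted p = 0.593 with an estimated correlation). Cd34 stood at 1130 ± 513 CPM in ADX against 2439 ± 125 CPM in Sham, and Krt15 at −0.94 (SE 0.29, edgeR adjusted p = 0.149). The calls of Ccnb2 and Birc5 were lost without Sham replicate 1 (edgeR adjusted p = 0.223 and 0.226), Sham replicate 2 (0.146 and 0.102) or ADX replicate 1 (0.175 for both).

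In all 43 genes rose and 2 fell in edgeR, against 574 and 267 in DESeq2 and 2318 at an unadjusted p under 0.05. Histone genes Hist1h2ab, Hist1h1b, Hist1h1d and Hist1h2ae rose by 5.10, 4.40, 3.27 and 3.12 (SE 0.93, 0.73, 0.51 and 0.50), and their near-identical copies make the counts uncertain. The division gene Cdkn3 (3.17, SE 0.54), the transporter Slco2b1 (3.25, SE 0.45) and Angptl4 (4.57, SE 0.83) rose, and so did the cornified envelope gene Sprr4 (3.58, SE 0.58). Krt35, a keratin of the hair shaft, had 214 reads in ADX and 1 in Sham, a ratio of 210 with a 95% counting interval of 37.3 to 8350. Slc14a1 fell by 2.07 (SE 0.34) and Chat, which makes acetylcholine, by 1.55 (SE 0.28). Their edgeR adjusted p-values were 0.0193 to 0.0455. Defb6 and Cst6 of the upper follicle (2.94 and 1.93) and the immediate early genes Nr4a1 and Egr2 (1.52 and 1.34) rose. Sebaceous gland genes rose in camera (13 of 14 higher, 5 risen when adjusted over the list alone, median 1.47, adjusted p = 5.53e-05, and adjusted p = 0.593 with an estimated correlation). Markers of immune cells (15 of 19 higher, median 1.24, camera adjusted p = 0.000186) and of endothelium (12 of 14 higher, median 1.48, camera adjusted p = 0.00133) rose in the same libraries, each with adjusted p = 0.593 with an estimated correlation. None of the genes named here passed without Sham replicate 1 or 2 (edgeR adjusted p-values 0.135 to 0.298 and 0.102 to 0.199), only Angptl4 and Defb6 did without ADX replicate 1 (0.059 to 0.261 for the others), and Nr4a1 and Egr2 did not without ADX replicate 2 (0.0531 and 0.0637). The count of 45 was 0, 3, 5 and 235 without Sham replicate 1, Sham replicate 2, ADX replicate 1 and ADX replicate 2, 70 with the replicate number as a block, 93 in a fit of only these 2 groups, and 21 with an offset for GC content and transcript length.

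**Figure D2:**
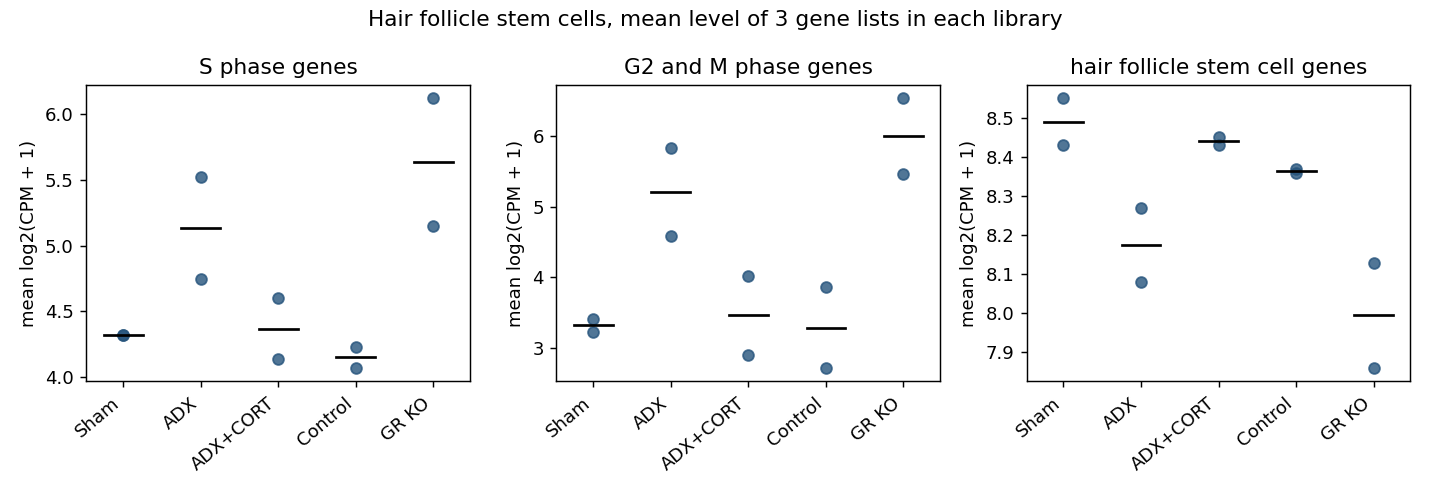
Mean log2(CPM + 1) of the genes of 3 lists (vertical axes, not starting at 0) in each of the 10 HFSC libraries, by group; points are libraries and bars are means of 2. The G2 and M phase list, with 34 of 34 genes higher in ADX than in Sham by the fitted values, had means of 5.47 and 6.54 in the GR KO libraries and 3.86 and 2.71 in the Control libraries.

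Corticosterone given after adrenalectomy was compared with adrenalectomy alone to see whether these values returned. No gene passed in edgeR (lowest adjusted p = 0.0573), 2941 had an unadjusted p under 0.05, and DESeq2 called 1318, of which 590 rose and 728 fell. The G2 and M phase list fell in camera, with 33 of 34 genes lower and 26 fallen when adjusted over the list alone (median −2.02, adjusted p = 2.22e-19, and adjusted p = 0.904 with an estimated correlation). Ccnb2 had a value of −2.41 (SE 0.53), Birc5 of −2.26 (SE 0.49), Ube2c of −2.62 (SE 0.52) and Kif23 of −2.31 (SE 0.48). S phase genes fell as a list (30 of 33 lower, 11 fallen when adjusted over the list alone, median −0.75, adjusted p = 1.23e-07, and adjusted p = 0.904 with an estimated correlation). So did mitochondrial respiratory chain genes (16 of 24 lower, 12 fallen when adjusted over the list alone, median −0.53, adjusted p = 3.95e-05, and adjusted p = 0.904 with an estimated correlation), with Cox5b at −1.38 (SE 0.26). Among genes with the smallest p-values were Hist1h2bc at −2.02 (SE 0.31), Mfap2 at −1.72 (SE 0.27), Lyz2 at −2.12 (SE 0.32), Dgat2, an enzyme of triglyceride synthesis, at 1.58 (SE 0.25) and Skiv2l at 1.49 (SE 0.22). Axl, a receptor of Gas6, had a mean of 182 CPM in ADX+CORT and 84.6 CPM in ADX, a log2 fold change of 1.10 (SE 0.25, edgeR adjusted p = 0.06), which passed without ADX replicate 2 (1.39, adjusted p = 0.0309). Without ADX HFSC replicate 2, 549 genes passed, and 884 did in a fit of the 6 libraries of the surgery experiment alone, an alternative chosen after the data were seen.

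Of the 45 genes called after adrenalectomy, 43 had the opposite sign in ADX+CORT against ADX, 33 of them at an unadjusted p under 0.05, and 29 ended nearer to Sham than to ADX. Opposite signs are built into this choice, because the ADX libraries enter both comparisons, and the 45 genes with the smallest p-values in 20 simulations of unchanged groups gave means of 43, 18 and 21.6 (ranges 42 to 45, 10 to 26 and 14 to 27). With simulated ADX and ADX+CORT groups of equal means, apart from Sham, the means were 31.8, 6.8 and 0.95. These simulations of the 45 genes were added after the data were seen. No gene was called in both with opposite signs in edgeR, against 481 in DESeq2 and 176 in edgeR without ADX HFSC replicate 2. At an unadjusted p under 0.05, 1400 genes were opposite in both. The 2 comparisons share the ADX libraries, and 20 simulations of unchanged groups gave a mean of 153 such genes and at most 179, while independent lists would share 223. All simulations of reversal drew genes independently, so they hold no noise shared by many genes of a library. They cannot bound these counts under such noise. The Pearson correlation of the log2 fold changes was −0.584 against −0.514 in the simulations (range −0.545 to −0.475), and their covariance was −1.28 against −0.414. In a fit added after the data were seen, 1 ADX library was compared with Sham and the other with ADX+CORT, each assumed to vary like the other groups. At an unadjusted p under 0.05, 683 genes were then opposite and 17 had the same sign with ADX replicate 1 against Sham, and 487 and 24 with ADX replicate 2 against Sham, where 20 simulations of unchanged groups gave at most 37 opposite genes. The correlations were −0.151 and −0.147 against simulated means of −0.0309 and −0.0352, and the covariances −0.449 and −0.441 against −0.0439 and −0.0497. In either split no gene was called in both with opposite signs in edgeR, nor in its simulations. Slc14a1 and Chat had values of 1.85 and 1.49 after corticosterone, while Angptl4, Slco2b1 and Egr2 had values of 0.32, −0.53 and −0.12.

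Against Sham, ADX+CORT HFSC had no gene past the threshold in edgeR (lowest adjusted p = 0.191), with 927 at an unadjusted p under 0.05 and 59 called by DESeq2. The counts in edgeR were 2 without Sham HFSC replicate 2 and 4 without ADX+CORT HFSC replicate 1. Differentiated epidermis genes rose as a list (18 of 18 higher, 5 risen when adjusted over the list alone, median 0.95, camera adjusted p = 4.73e-16), as did sebaceous gland genes (14 of 14 higher, 6 risen when adjusted over the list alone, median 1.92, adjusted p = 3.75e-09) and immediate early and heat shock genes (18 of 21 higher, 6 risen when adjusted over the list alone, median 0.44, adjusted p = 1.41e-07). Ribosome biogenesis genes fell (19 of 24 lower, median −0.31, adjusted p = 5.22e-05). For each of these lists adjusted p = 0.4 with an estimated correlation. Markers of endothelium (14 of 14 higher, camera adjusted p = 1.32e-05), dermal fibroblasts (14 of 20, 0.0162), immune cells (16 of 19, 0.0173) and melanocytes (8 of 11, 0.0345) rose too. Skeletal muscle genes fell (9 of 10 lower, camera adjusted p = 0.00839). These had adjusted p = 0.4 to 0.417 with an estimated correlation. Dermal papilla, pericyte, Schwann cell and adipocyte lists did not pass. Angptl4 stood at 74.3 ± 12.0 CPM against 2.52 ± 1.23 CPM (4.89, SE 0.84), Hspa1b at 1.58 (SE 0.30) and Krt79 at 1.47 (SE 0.43). The G2 and M phase list had a median of 0.22 (camera adjusted p = 0.325).

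GR deletion in dermal cells was followed by changes in HFSC, which tests whether the receptor in the dermis bears on the stem cells. The loss of Nr3c1 was seen in the DP libraries. Those held Xist, while the Control and GR KO HFSC libraries held Y-linked reads and almost no Xist. The 2 cell types thus appear to come from different animals, and dermal deletion was not checked in those that gave the HFSC. Cell division genes rose most in HFSC. Of 34 G2 and M phase genes 14 rose and 20 did not pass, and 34 rose when adjusted over the list alone (median 2.90, camera adjusted p = 1.16e-51, and adjusted p = 0.336 with an estimated correlation). Ccnb2 rose from 11.1 ± 6.46 to 105 ± 44.0 CPM (SD, n = 2 each; log2 fold change 3.25, SE 0.54, edgeR adjusted p = 0.0327), Kif11 by 3.44 (SE 0.51) and Cenpf by 3.55 (SE 0.71). Of 33 S phase genes 7 rose and 28 rose when adjusted over the list alone (median 1.53, camera adjusted p = 4.53e-28, and adjusted p = 0.336 with an estimated correlation), among them E2f1 (2.74, SE 0.49) and Mcm6 (1.98, SE 0.30). Cd34, a surface marker of bulge stem cells, fell by 1.49 (SE 0.29, adjusted p = 0.0384), and the HFSC list fell with it (19 of 27 lower, 8 fallen when adjusted over the list alone, median −0.24, camera adjusted p = 0.000166, and adjusted p = 0.336 with an estimated correlation). The hair germ genes Cux1 and Mycn rose by 2.31 (SE 0.33) and 2.38 (SE 0.40). None of the genes named here passed without Control replicate 2 (edgeR adjusted p-values 0.151 to 0.206), and Kif11, E2f1, Mcm6, Cd34 and Mycn did not without Control replicate 1 (0.0506 to 0.0765). Without GR KO replicate 2, Ccnb2, Cenpf, E2f1, Cd34 and Mycn did not pass (0.0541 to 0.121).

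In edgeR 102 genes rose and 48 fell, against 443 and 274 in DESeq2. Of 18 differentiated epidermis genes 4 rose, 1 fell and 10 rose when adjusted over the list alone (median 1.16, camera adjusted p = 5.59e-09, and adjusted p = 0.336 with an estimated correlation). Krt79 and Cst6 rose by 2.31 and 1.84, and Lor fell by 1.88. Immediate early and heat shock genes fell as a list (20 of 21 lower, 11 fallen when adjusted over the list alone, median −0.80, adjusted p = 1.69e-12, and adjusted p = 0.336 with an estimated correlation). Hspa1b and Hspb1 fell by 1.63 and 1.24, while Egr2 rose by 1.14. Dermal fibroblast genes fell as a list (18 of 20 lower, 4 fallen when adjusted over the list alone, median −1.11, adjusted p = 9.73e-07, and adjusted p = 0.336 with an estimated correlation). Plvap, a marker of endothelium, and Klf15, a glucocorticoid target, fell with log2 fold changes of −3.16 and −2.18. Gfra2 fell by 2.30 (SE 0.29, edgeR adjusted p = 0.0162) and Tmtc1 by 2.11 (SE 0.33). Among the genes named here only Gfra2 passed without Control replicate 2 (0.0807 to 0.227 for the others in edgeR) and only Gfra2 and Lor without Control replicate 1 (0.0506 to 0.117). Krt79, Lor and Egr2 did not pass without GR KO replicate 1 (0.0508 to 0.121), nor Lor, Hspa1b, Hspb1, Egr2, Plvap, Klf15 and Tmtc1 without GR KO replicate 2 (0.0513 to 0.181). The count of 150 was 27 without Control HFSC replicate 1, 5 without Control HFSC replicate 2, 336 without GR KO HFSC replicate 1 and 57 without GR KO HFSC replicate 2. The 4 Control and GR KO libraries, labelled female, held 0 to 3 reads of Xist and 111 to 172 CPM over 4 Y-linked genes, whereas the 6 HFSC libraries of the surgery experiment held 122 to 255 CPM of Xist and no Y-linked read.

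Adrenalectomy and dermal GR deletion shared 15 risen and 2 fallen genes in HFSC, where independent lists of these sizes would share 0.29 and 0.01 (Fisher's exact test, p = 1.09e-22 and 9.73e-06). These p-values treat genes as independent, which genes that change together are not. Over all genes tested, the log2 fold changes of both comparisons had a Pearson correlation of 0.093 and a Spearman correlation of 0.18. The comparisons use different control libraries. Shared risen genes were Krt35, Hist1h2ab, Hist1h1b, Ccnb2, Hist1h2ae, Cdkn3, Birc5, Cks2, Gsdma3, Stmn1, Defb6, Cst6, Cux1, Sprr1a and Egr2, and both fallen genes were Slc14a1 and Chat. DESeq2 gave 177 shared calls. No gene differed between both effects in edgeR (lowest adjusted p = 0.104), with 1610 at an unadjusted p under 0.05 and 108 in DESeq2. These effects were measured in libraries of different apparent sex, as given above, and a dependence on sex, strain or tamoxifen was not tested. In camera 15 lists differed. Immediate early and heat shock genes were more positive after adrenalectomy in 21 of 21 (median difference 1.31, adjusted p = 2.07e-18, and adjusted p = 0.3 with an estimated correlation). The division lists that rose in both comparisons rose less after adrenalectomy, with 30 of 34 G2 and M phase genes lower (median difference −0.72, adjusted p = 0.000496, and adjusted p = 0.603 with an estimated correlation) and 23 of 33 S phase genes (−0.77, adjusted p = 0.000224, and adjusted p = 0.575 with an estimated correlation). Neither passed without ADX replicate 2 or GR KO replicate 2, nor the G2 and M phase list without Control replicate 2 (adjusted p up to 0.493). The shared count of 17 was 0 without either Sham replicate, 1 without ADX replicate 1, 78 without ADX replicate 2, 5 and 2 without Control replicates 1 and 2, and 44 without GR KO replicate 1. The count of differing genes was 1 without Sham replicate 2, 4 without ADX replicate 1, 3 without Control replicate 2 and 20 without GR KO replicate 1.

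**Figure D3:**
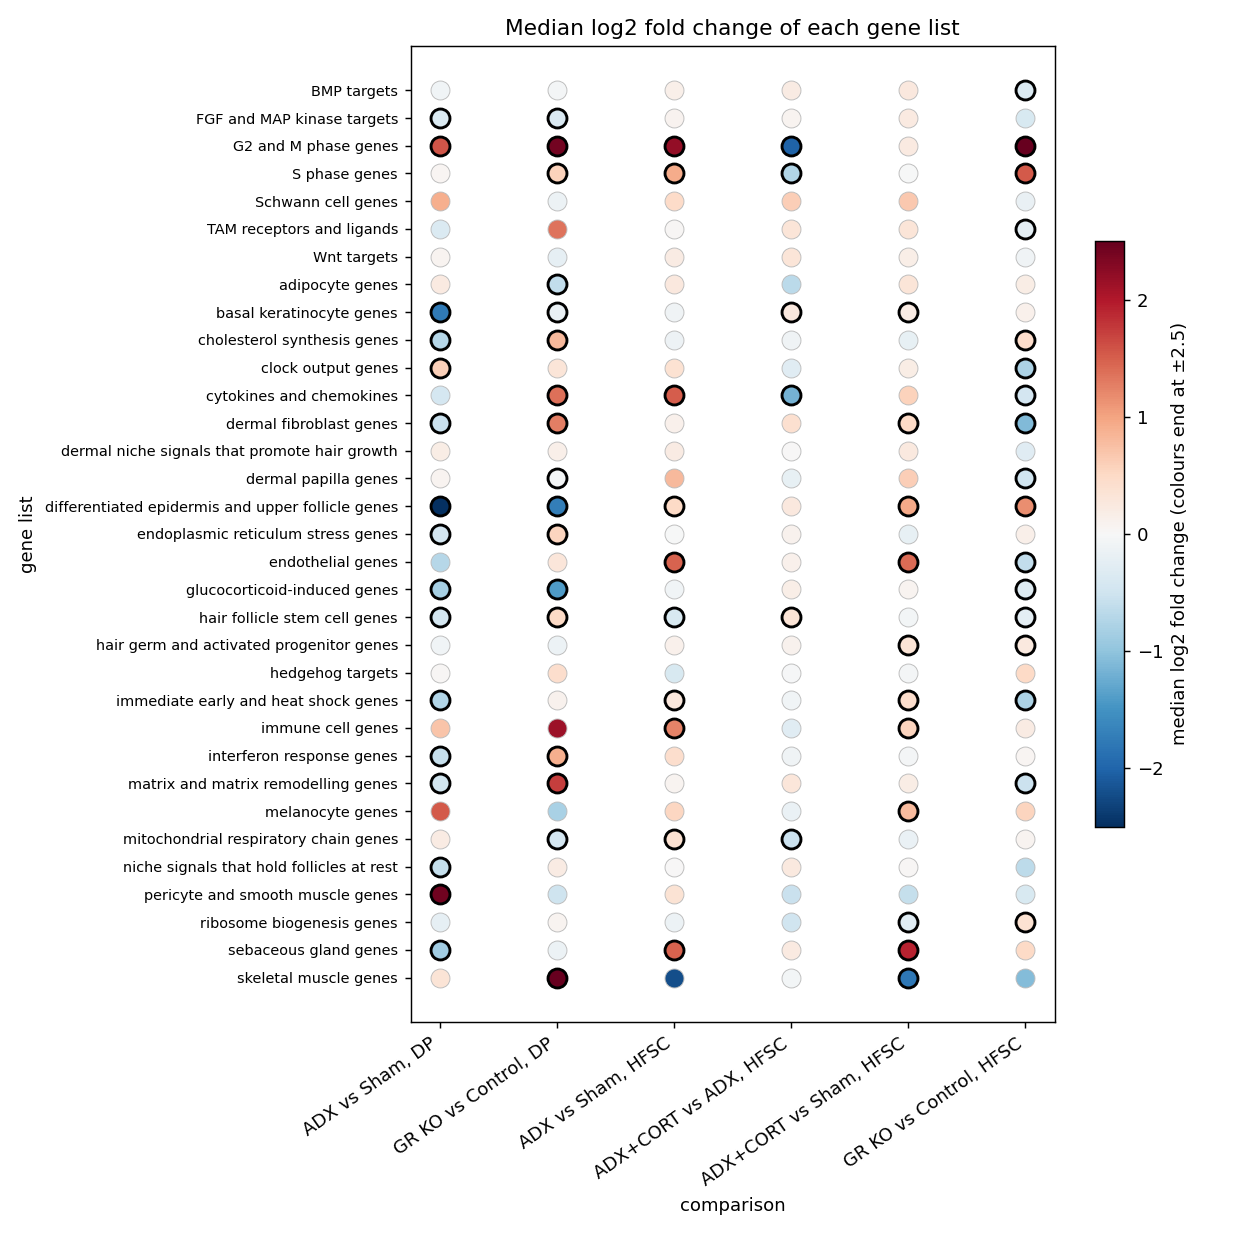
Median log2 fold change (colour) of each of the 33 gene lists (vertical axis) in the 6 comparisons (horizontal axis); black rims mark lists with a camera adjusted p under 0.05 at a preset correlation of 0.01. The G2 and M phase list had medians of 2.19 and 2.90 in HFSC after adrenalectomy and GR deletion and −2.02 in ADX+CORT against ADX, and no list passed with an estimated correlation.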

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

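In this part the tests of fibroblast carry-over and of the share of dermal papilla cells, the latter in 3 forms (on the basal keratinocyte list, on the differentiated epidermis list and on the gap between lists), were chosen only after the results were seen, and the offset for GC content and transcript length was added after the data were seen.

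Adrenalectomy and GR deletion had different effects in DP for 112 genes, by a test of the difference itself in edgeR. The experiments also differ in strain and tamoxifen, so differences between these effects cannot be assigned to surgery against deletion alone. More positive after adrenalectomy were the sodium channel subunit Scnn1g (difference of log2 fold changes 11.45), the cartilage matrix protein Matn1 (11.16), the synuclein Sncb (6.40), the receptor partner Ramp3 (5.19) and Extl1 (4.74). More positive after GR deletion were Ptgs2 (−8.48), the serpins Serpinb2 (−8.15) and Serpina3n (−4.78), the kinase Camkk1 (−5.15) and Postn (−4.53). The edgeR adjusted p-values were 0.0156 to 0.0463. Scnn1g and Matn1 had means of 0.04 and 0.12 CPM in Sham, so the sizes of their differences depend on the prior count. Without Sham replicate 2 each of these calls except that of Scnn1g was lost (edgeR adjusted p 0.0796 to 0.103), and without Control replicate 2 each except those of Scnn1g and Ramp3 (0.0592 to 0.221). Ptgs2, Sncb, Camkk1 and Extl1 were also lost without Sham replicate 1 (0.0533 to 0.0656), and these 4 with Serpinb2 without Control replicate 1 (0.0518 to 0.087). Without ADX replicate 2 the same 5 and Postn were lost (0.0537 to 0.109), without ADX replicate 1 Camkk1 (0.0638), and without GR KO replicate 1 Ptgs2 and Camkk1 (0.108 and 0.0783). The count of 112 was 3 without Sham replicate 2 or Control replicate 2, 19 without ADX replicate 2, 26 without Control replicate 1 and 221 without GR KO replicate 2.

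The same test of the difference, run over gene lists with camera, called 10 lists in DP. More positive after GR deletion were the matrix genes, with a median difference of −2.38 (32 of 32, adjusted p = 1.33e-27, and adjusted p = 0.0778 with an estimated correlation), the dermal fibroblast genes with −1.96 (18 of 20, adjusted p = 1.91e-12) and the cholesterol synthesis genes with −1.62 (18 of 18, adjusted p = 1.63e-11). So were interferon response genes (−1.71, 20 of 22, adjusted p = 1.25e-07), endoplasmic reticulum stress genes (−1.24, 17 of 18, adjusted p = 4.94e-05), hair follicle stem cell genes (−1.34, 20 of 25, adjusted p = 0.000128), cytokines and chemokines (−1.62, 20 of 22, adjusted p = 0.00167) and immediate early and heat shock genes (−0.78, 17 of 21, adjusted p = 0.0124). More positive after adrenalectomy were pericyte and smooth muscle genes (3.17, 12 of 13, adjusted p = 6.11e-07) and mitochondrial respiratory chain genes (0.67, 19 of 24, adjusted p = 0.000216). For the other 9 lists adjusted p = 0.229 to 0.711 with an estimated correlation. The immediate early list was lost without ADX replicate 1 or Control replicate 1 (adjusted p up to 0.588), and the other 9 passed without each library, with median-of-ratios scaling and with the replicate block.

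The higher matrix genes in GR KO DP were set against technical explanations. With an offset for GC content and transcript length their median was 1.66 against 1.72 without it (lower quartile 1.13, camera adjusted p = 9.14e-27), which argues against such a trend as the whole cause. Dermal fibroblasts carried over in the flow cytometric sort are a candidate source, since the 16 fibroblast genes not on the matrix list had a median of 0.72 and 11 of them were higher in both GR KO libraries than in both Control libraries, with 4 of the 20 on both lists. The most abundant genes of the fibroblast list were Col3a1 (23885 ± 1875 CPM in GR KO and 5506 ± 2367 CPM in Control, SD, n = 2) and Col1a2 (17621 ± 1936 and 3883 ± 1843 CPM), and Dcn, which is not on the matrix list, stood at 11053 ± 5190 and 6513 ± 270 CPM. Dcn encodes a matrix protein too, so leaving out the 4 shared genes does not separate carry-over from higher matrix expression. A lower share of dermal papilla cells and an effect of GR deletion on matrix genes themselves stay open, because the dermal papilla list (median −0.05, camera adjusted p = 0.0498) and the lists of other cell types that passed downward in camera had upper quartiles above 0, namely basal keratinocyte (−0.19, adjusted p = 0.0307), adipocyte (−0.61, adjusted p = 0.00708) and differentiated epidermis genes (−1.72, adjusted p = 6.18e-10), with adjusted p = 0.39 to 0.669 with an estimated correlation, while the pericyte list (11 of 13 lower, median −0.51, upper quartile −0.06) did not pass (adjusted p = 0.108), and each of the 8 gaps between the quartiles of 2 lists changed sign without some library, as between immune and pericyte genes (1.75, and −3.08 without GR KO replicate 1) and between fibroblast and pericyte genes (0.63, and −0.69 without Control replicate 1).

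The dermal papilla list was lost without Control replicate 2 or GR KO replicate 2 and with the replicate block (camera adjusted p up to 0.697), the adipocyte list without Control replicate 1 or GR KO replicate 2 (up to 0.246), and the basal keratinocyte list without the same 2 libraries (up to 0.601).

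In HFSC the same test called 15 lists. There the surgery libraries held Xist and no Y-linked read, and the Control and GR KO libraries held Y-linked reads and almost no Xist, so the 2 effects were measured in libraries of different apparent sex, and a dependence on sex was not tested. Strain and tamoxifen differ between these experiments as well. More positive after adrenalectomy were immediate early and heat shock genes, with a median difference of 1.31 (21 of 21, camera adjusted p = 2.07e-18, and adjusted p = 0.3 with an estimated correlation), cytokines and chemokines (1.82, adjusted p = 1.49e-07), endothelial (2.27, 9.04e-06), clock output (1.46, 0.000136), dermal fibroblast (0.67, 0.000136), dermal papilla (1.06, 0.000772), immune cell (0.79, 0.00246) and sebaceous gland genes (0.91, 0.00686), BMP targets (0.72, 0.00843) and FGF and MAP kinase targets (0.60, 0.0118). More positive after GR deletion were S phase (−0.77, 0.000224), cholesterol synthesis (−0.72, 0.000388), G2 and M phase (−0.72, 0.000496) and ribosome biogenesis genes (−0.38, 0.00749) and hedgehog targets (−0.98, 0.0104). For the other 14 lists adjusted p = 0.0889 to 0.603 with an estimated correlation. The immediate early, cytokine, endothelial, clock output and fibroblast lists passed without each library, with median-of-ratios scaling and with the replicate block. Calls were lost without Sham replicate 1 for the immune list, without Sham replicate 2 for the BMP, FGF, cholesterol and ribosome biogenesis lists, and without ADX replicate 2 for the S phase, G2 and M phase, sebaceous, FGF and ribosome biogenesis lists. They were lost without Control replicate 1 for the dermal papilla, BMP, FGF, cholesterol and ribosome biogenesis lists, and without Control replicate 2 for the G2 and M phase, sebaceous and hedgehog lists. Without GR KO replicate 1 the immune and BMP lists were lost, and without GR KO replicate 2 the S phase, G2 and M phase, sebaceous, FGF, hedgehog and ribosome biogenesis lists (adjusted p up to 0.493 over these fits).

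Y-linked genes, which were not left out of the fits, gave a signal in HFSC libraries labelled female, with 110.53 to 172.06 CPM over 4 genes in the Control and GR KO libraries and no read in the 6 libraries of the surgery experiment.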

How the results depend on the processing

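Counts of called genes depended on the tool and on single libraries. For named genes other than Gas6 and Nr3c1 in DP, 297 values had 2736 values under alternatives, of which 1968 stayed on the same side of the threshold, 312 gained a call and 456 lost one, 365 of these by leaving out a library. A called gene changed its sign in 0 of them. Of the 134 that were called, 127 lost the call when some library was left out and 6 kept it in every alternative run. The cause was not tested for the changed results below, unless given. Median-of-ratios scaling moved none of the counts of called genes or lists by over 1.5 times, but it moved the split of risen and fallen genes after GR deletion in DP from 180 and 181 to 134 and 247, and of more positive and more negative genes for the difference in DP from 30 and 82 to 45 and 46. Depth limits genes of low count, whose fold changes depend on the prior count.

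In edgeR without the filter on low counts, 894 genes in place of 4 were called after adrenalectomy in DP, 1456 in place of 361 after GR deletion in DP and 1305 in place of 112 for the difference. In HFSC the counts were 888 in place of 45 after adrenalectomy, 1309 in place of 0 for ADX+CORT against ADX, 184 in place of 0 for ADX+CORT against Sham, 840 in place of 150 after GR deletion and 256 in place of 0 for the difference. DESeq2 called 467, 1373, 1055, 841, 1318, 59, 717 and 108 in that order, where edgeR had 2737, 3574, 3596, 2318, 2941, 927, 1998 and 1610 genes at an unadjusted p under 0.05. Genes shared between adrenalectomy and GR deletion were 149 without the filter and 61 with DESeq2 in place of 1 in DP, and 267 and 177 in place of 17 in HFSC. Calls of adrenalectomy reversed by corticosterone were 515 and 481 in place of 0. Gas6 passed the threshold without the filter and with DESeq2, at 1.85 (adjusted p = 5.91e-07) and 1.93 (adjusted p = 0.000308) after adrenalectomy and at 1.42 (adjusted p = 0.000233) and 1.48 (adjusted p = 0.00467) after GR deletion, in place of 1.87 and 1.57 in edgeR (adjusted p = 0.183 and 0.0734).

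With only the 2 groups compared in a fit, edgeR called 0 genes after adrenalectomy in DP, 142 after GR deletion in DP, 93 after adrenalectomy in HFSC and 2 for ADX+CORT against Sham. Such a fit rests on fewer libraries. With an estimated correlation camera called 0 lists in each of 6 comparisons, in place of 16 and 17 in DP, and 10, 6, 11 and 17 in HFSC.

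The offset for GC content and transcript length, protein-coding genes alone, libraries of the same experiment alone, crossed numbers and the split of the ADX libraries were chosen after the data were seen. With the offset 217 genes were called after GR deletion in DP, 57 for the difference in DP and 21 after adrenalectomy in HFSC. Protein-coding genes alone gave 197 for the difference in DP, with fewer genes tested. Libraries of the surgery experiment alone gave 146 after adrenalectomy in HFSC and 884 for ADX+CORT against ADX. With the ADX HFSC libraries split between the comparisons, 0 calls were reversed either way.

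The samples share only a replicate number, and the correlations of deviations between samples of the same number were −0.148 and 0.22 for adrenalectomy and GR deletion in DP, and −0.02, 0.041, 0.016 and 0.02 in HFSC. With the number as a block, edgeR called 7 genes after adrenalectomy in DP and 70 in HFSC, against 318 after GR deletion in DP, 80 for the difference in DP and 191 after GR deletion in HFSC, which moved by less than 1.5 times. With crossed numbers, 100 genes in place of 4 were called after adrenalectomy in DP.

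Leaving out each library in turn gave 1 to 12 genes after adrenalectomy in DP (1 without Sham replicate 2, 12 without ADX replicate 2), 19 to 226 after GR deletion (19 without Control replicate 2), 3 to 221 for the difference and 0 to 5 shared. In HFSC it gave 0 to 235 after adrenalectomy (0, 3 and 5 without Sham replicates 1 and 2 and ADX replicate 1, 235 without ADX replicate 2), 0 to 549 for ADX+CORT against ADX (549 without ADX replicate 2) and 0 to 4 against Sham. After GR deletion in HFSC it gave 5 to 336 (27 and 5 without Control replicates 1 and 2, 336 and 57 without GR KO replicates 1 and 2), with 0 to 20 for the difference, 0 to 78 shared and 0 to 176 reversed. Gas6 was 1.66 to 2.03 after adrenalectomy and 0.90 to 2.04 after GR deletion (adjusted p = 0.0304 without GR KO replicate 2, 0.381 to 0.473 without the others). Nr3c1 was −0.62 to 0.27 after adrenalectomy, with the sign reversed at 0.27 without Sham replicate 1 and no call in any of these fits, and −3.13 to −2.58 after GR deletion, with the call lost at −2.62 without Control replicate 2 (adjusted p = 0.0589, against 0.0211 to 0.0493 without the others). Lists called numbered 13 to 15 and 14 to 20 in DP, and 8 to 14, 5 to 10, 10 to 15 and 8 to 17 in HFSC.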

Other observations

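In this part the test of fibroblast carry-over was chosen only after the result was seen, and the offset for GC content and transcript length was added after the data were seen.

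Further lists passed in camera in 1 or both of the DP comparisons. Endoplasmic reticulum stress genes fell in camera after adrenalectomy (16 of 18 lower, median −0.46, adjusted p = 0.000164, and adjusted p = 0.414 with an estimated correlation), with the chaperone Hspa5 at 361 ± 88.8 CPM in ADX and 772 ± 75.6 CPM in Sham. After GR deletion they rose (15 of 18 higher, median 0.55, adjusted p = 0.0111, and adjusted p = 0.52 with an estimated correlation), but not without Control replicate 1 (adjusted p = 0.365). Interferon response genes fell after adrenalectomy (17 of 22 lower, median −0.57, adjusted p = 0.000928, and adjusted p = 0.414 with an estimated correlation). Cytokines and chemokines rose after GR deletion (17 of 22 higher, 6 risen when adjusted over the list alone, median 1.38, adjusted p = 0.00629, and adjusted p = 0.407 with an estimated correlation), but not without GR KO replicate 1 (adjusted p = 0.144), and did not pass after adrenalectomy (median −0.43, adjusted p = 0.13). Immune cell genes were also higher after GR deletion (18 of 18, median 2.13, camera adjusted p = 0.149), but lower without GR KO replicate 1 (median −2.84). Niche signals that hold follicles at rest fell after adrenalectomy (13 of 17 lower, median −0.60, adjusted p = 0.0447, and adjusted p = 0.497 with an estimated correlation), with the Wnt inhibitor Sfrp2 at 57.9 ± 26.7 CPM in ADX and 298 ± 10.7 CPM in Sham. That list was lost without Sham replicate 1 or ADX replicate 1 and with the replicate block (adjusted p up to 0.508), and it did not pass after GR deletion (9 of 17 higher, median 0.20, adjusted p = 0.941). Ribosomal protein genes were lower after GR deletion, with 103 of 112 lower, 43 fallen in edgeR and a median of −1.52, or −1.03 with the offset for GC content and transcript length. After adrenalectomy 99 of 112 were higher, with no call in edgeR and a median of 0.39, or 0.34 with the offset. Niche signals that promote hair growth did not pass in either comparison (medians 0.19 and 0.15, camera adjusted p = 0.142 and 0.913).

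In HFSC, cytokines and chemokines rose in camera after adrenalectomy (16 of 21 higher, median 1.51, adjusted p = 0.000129, and adjusted p = 0.376 with an estimated correlation), with the chemokine Cxcl10 at 16.0 ± 4.79 CPM in ADX and 0.93 ± 0.51 CPM in Sham. Clock output genes fell after dermal GR deletion (12 of 12 lower, 3 fallen when adjusted over the list alone, median −0.80, adjusted p = 0.000243, and adjusted p = 0.402 with an estimated correlation). Nr1d1, a repressor of the circadian loop, stood at a mean of 120 CPM against 355 CPM, and Dbp at 48.6 CPM against 239 CPM. Without GR KO replicate 2 the adjusted p of this list rounded to 0.05 and it did not pass. Cholesterol synthesis genes rose after GR deletion (18 of 18 higher, median 0.45, adjusted p = 0.00121, and adjusted p = 0.462 with an estimated correlation), but not without Control replicate 1 (adjusted p = 0.187). In ADX+CORT against Sham, endothelial genes rose (14 of 14 higher, median 1.42, adjusted p = 1.32e-05, and adjusted p = 0.4 with an estimated correlation), but not without ADX+CORT replicate 1 (adjusted p = 0.117). Glucocorticoid-induced genes did not pass in HFSC after adrenalectomy (median −0.08, camera adjusted p = 0.936) or in ADX+CORT against ADX (median 0.17, adjusted p = 0.933). They fell after dermal GR deletion (19 of 28 lower, 2 fallen in edgeR, median −0.33, adjusted p = 0.0262, and adjusted p = 0.605 with an estimated correlation), but not without Control replicate 1 or GR KO replicate 2 (adjusted p up to 0.77).

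The higher Gas6 in DP was set against technical explanations. With an offset for GC content and transcript length its log2 fold change was 2.12 (SE 0.37) after adrenalectomy and 1.63 (SE 0.37) after GR deletion, more than 2 SE above 0 in both, which argues against such a trend as the whole cause. After adrenalectomy the offset turned the GC trend rather than removing it. The Spearman correlation of log2 fold changes with GC content was −0.148 without the offset and 0.095 with it. Gas6 was higher in ADX under either sign of that trend. Carry-over of dermal fibroblasts in the flow cytometric sort would raise their genes. After adrenalectomy the median of these 20 genes was −0.55 (camera adjusted p = 4.49e-06, and adjusted p = 0.414 with an estimated correlation). The abundant Col3a1 and Dcn stood at 6432 ± 1033 and 3819 ± 1161 CPM in ADX against 9603 ± 2357 and 8880 ± 212 CPM in Sham. These values show no rise of fibroblast genes. They cannot decide on carry-over, because the matrix list fell as well (median −0.47) and lower expression in the sorted cells could hide it. After GR deletion carry-over of fibroblasts stays a candidate source, with a median of 1.28 (camera adjusted p = 2.98e-08, and adjusted p = 0.291 with an estimated correlation). Col3a1 stood at 23885 ± 1875 against 5506 ± 2367 CPM and Dcn at 11053 ± 5190 against 6513 ± 270 CPM, and 4 of the 20 genes were also on the matrix list. Gas6 stood at 1333 and 607 CPM in GR KO replicates 1 and 2. Without replicate 1 the immune, basal keratinocyte and Schwann cell lists had medians of −2.84, −5.42 and −2.13. With all libraries these were 2.13, −0.19 and −0.14. The fibroblast list stayed at 1.12 without replicate 1. Carry-over of immune cells, keratinocytes or Schwann cells was not tested and stays open. Pericyte and smooth muscle genes rose in DP after adrenalectomy (10 of 13 higher, median 2.44, camera adjusted p = 1.88e-06, and adjusted p = 0.414 with an estimated correlation). After GR deletion they did not (median −0.51, camera adjusted p = 0.108). Carry-over of those cells was not tested as a source of the higher Gas6 and stays open after adrenalectomy. A release of Gas6 from corticosterone acting through GR, which the groups were made to test, remains a hypothesis in both comparisons, and edgeR did not call either change.

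The higher division and ribosomal protein genes in HFSC after adrenalectomy were weighed against a trend with GC content and transcript length, with no other explanation tested. The G2 and M phase genes had a median of 2.14 with the offset (lower quartile 1.93, camera adjusted p = 1.39e-28) against 2.19 without it, which argues against the trend as the whole cause. Ribosomal protein genes, 82 of 90 of them higher, had a median of 0.94 without the offset and 0.49 with it (lower quartile 0.30), and in ADX+CORT against ADX, with 84 of 90 lower, −1.01 and −0.51 (quartile nearer 0 at −0.20), while ADX+CORT against Sham gave −0.08. Whether more than 0.5 of the uncorrected median was left depended on which genes were counted, at 51.6% with the definition written first and 47.1% and 56.8% with the others after adrenalectomy, and 50.8%, 44.4% and 51.8% after corticosterone. The trend and a change by corticosterone cannot be told apart for these genes, because the quartiles cross that bound.

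The 8 DP libraries, labelled female, held 249 to 620 CPM of Xist. Over the 4 Y-linked genes they held 9.89 and 26.4 CPM in Sham, 43.8 and 28.9 CPM in ADX, and 2.71 to 3.68 CPM in Control and GR KO.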
